A study of Mus musculus with 1000 samples.

How the data were processed

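Brains, without the cerebellum, of generation 3 mice descended from males treated with N-ethyl-N-nitrosourea (ENU, a chemical mutagen that introduces point mutations) were profiled by 3′ RNA sequencing. Per the labels' protocols, founders of the C57BL/6NCrl strain received 3 doses of 100 mg/kg. Offspring were usually collected at 8 to 12 weeks, and the cerebellum was removed before RNA extraction, although the labels call the tissue whole brain. Each cDNA synthesis began from 4 ng of RNA and used an in-line index. The 12 samples of a plate row were then pooled, and 96 such pools from 12 plates made a library of 1152 samples. GSNAP and the GRCm38 assembly are named in the submitters' processing notes, without a version or a role.

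The table deposited by the authors and used here is a lookup sheet. It pairs a library name with the name of 1 of 3 expression files beside an unnamed column of row numbers, and holds no count or expression value per gene. The expression files themselves were not analysed here. Depth per sample, differences in expression and the inflammatory state of any animal are therefore not reported. The tests and gene lists fixed before the data were examined for a comparison of expression between groups were not run, and no gene is named. The annotation was not used.

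Each library name was split into its parts with Python 3.11.15 and pandas 2.3.3. These parts are a leading group name, an animal number, a plate row and column, a plate number and a number after the letter S. The group was the text before G3, and the animal number was the digits after G3. This split (G328 as G3 and 28) was read from the form of the names and is an assumption that the labels do not state. The labels do not state that this text names a pedigree. They do state that 12 siblings were typical of a pedigree, and this was set beside the group sizes. A cDNA pool was taken as 1 row of 1 plate, after the labelled protocol. Libraries were joined to the sheet by their whole name. The values are complete counts of names, so no test was made and no sampling error applies. Repeated counts changed the part of the name used for the join, the definition of a pool, and the set of groups. The figure was drawn with matplotlib 3.10.9.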

Results

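The series comprised 1000 RNA libraries from ENU-mutagenized mice, made from brain without the cerebellum. The stated aim was to find abnormal inflammatory states in a large cohort. No expression values were analysed here, so the results concern the arrangement of these libraries and the comparisons that this arrangement permits. The labels named no control or treated group. Animals were divided here by the leading part of each library name, a reading that the labels do not state.

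The 1000 libraries fell into 88 groups by this leading name. Of these groups, 80 had 12 libraries, the number of siblings that the labels gave as typical of a pedigree. A further 6 groups had 6 libraries, 1 had 3 and 1 had 1. A full plate row also holds 12 samples, so a group size of 12 does not by itself show that a group is a pedigree. Animal numbers, read as the digits after G3 in the name, ran from 1 to 36, and the number of animals appearing more than once within a group was 0. By this reading of the names, no animal had a repeat library in the series.

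The libraries occupied 86 rows on 18 plates. The 12 plates named neuro2184 to neuro2195 carried 927 libraries (92.7%) from 80 groups. The 6 plates named neuro2197 to neuro2207 carried the other 73 libraries (7.3%) from 8 groups. These counts cover only libraries of this series and do not show how full the plates were. The S number in the name equalled the rank of the row among the rows of a set of 12 plates, with 8 rows per plate, for 927 of 927 and 73 of 73 libraries. The S numbers therefore began again once, between neuro2195 and neuro2197. In the second set the rank was counted as if the set began at the plate number after neuro2195, which no library of this series carried.

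The names permit a comparison of 1 group of animals with another, and a comparison among animals of 1 group, treated below. Each of the 88 groups lay on 1 plate and in 1 row of that plate (100.0% of groups). Because the 12 samples of a row were pooled after cDNA amplification, each group passed through library preparation in a single pool. Of the 86 rows, 84 held libraries of 1 group in this series and 2 rows (2.33%) held libraries of 2 groups. For the 84 groups that did not share a row, a difference in expression from another group of this series would also be a difference between pools. Between groups on different plates, it would be a difference between plates as well. The 80 groups on plates neuro2184 to neuro2195 and the 8 groups on plates neuro2197 to neuro2207 were separate. A comparison of the 80 with the 8 would thus also be a comparison of sets of plates. If each set made 1 library of 12 plates, as in the protocol, it would compare libraries too. The group names were also separate, from ENU56055B6 to ENU57022B6 for the 8 and from ENU57189B6 to ENU58096B6 for the 80.

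Groups that shared a pool in this series numbered 4. In row D of plate neuro2188, ENU57446B6 occupied columns 1 to 6 and ENU57317B6 occupied columns 7 to 12. In row H of plate neuro2201, ENU56462B6 occupied columns 1 to 6 and ENU56135B6 occupied columns 7 to 12. Each of these groups had 6 libraries. Comparisons within these rows would be free of a difference in pool, but the groups had separate columns, and per the labels each sample of a row had its own in-line index. Comparisons among animals of 1 group would also lie within 1 pool. Those animals likewise had separate columns, each with its own in-line index.

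**Figure D1:**
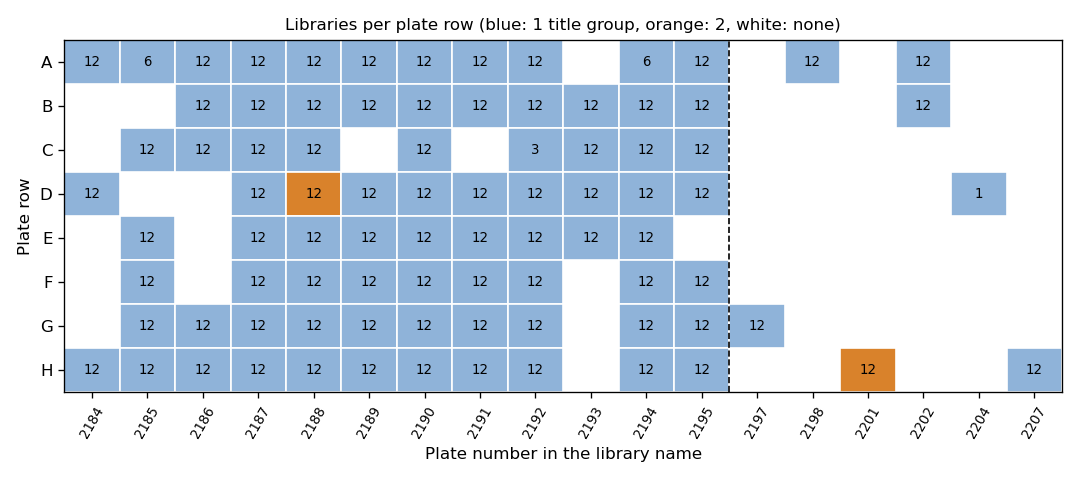
Number of libraries in each plate row (vertical axis, rows A to H) of each plate (horizontal axis, plate number from the library name), with a dashed line between the 2 sets of plates. Blue rows hold 1 group of this series, the 2 orange rows hold 2 groups, and white positions hold no library of this series. Of the 86 rows, 82 hold 12 libraries of this series. Libraries outside the series are not counted. With them, each row that has fewer than 12 here had 12 entries in the lookup sheet.

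All 1000 library names were present in the lookup sheet, which listed 23231 libraries under names that were each used once. Every one of the 1000 was assigned to the third of 3 expression files. That file was listed for 7745 libraries, against 7743 for each of the other 2. All libraries of this series thus pointed to 1 expression file, and no comparison among them would cross files.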

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

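The libraries were also joined to the sheet by the number at the end of the name, and by the name without that number. Each join matched 1000 libraries, as did the whole name. Because all whole names matched, these joins could fail only where a part of a name was repeated in the sheet. They showed only that these parts were not repeated. All 691 groups among the 7775 sheet entries with names of the same form lay in 1 pool. Defining a pool by the S number alone, or keeping only the 80 groups of 12 libraries, could not have split a group and so tested nothing about this. The share of pools holding 2 or more groups was 2.33% as reported. It was 10.1% (8 of 79) by the S number alone, because 7 S numbers occurred in both sets of plates. It was 0.0% (0 of 80) with groups of 12 libraries only, which fill a row, and 6.64% (43 of 648) over the sheet entries of the same form. The alternatives planned for a comparison of expression (normalization, filtering, pseudocount, omission of single replicates) were not run, since no expression values were analysed. No paired analysis was possible because the results come from no test, and nothing in the labels ties an animal number in one group to the same number in another.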

Other observations

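The values in this part were examined only after the sheet had been seen. The 1000 libraries filled positions 20001 to 21000 of the sheet without a gap. This range divided 2 groups from the rest of their entries. Sheet entries of a group were counted only among names of the same form as those of the series. By this count, ENU57189B6 had 3 libraries in the series and 12 in the sheet, and ENU57022B6 had 1 in the series and 6 in the sheet. The 14 entries outside the series were not analysed here. The range thus reduced the size of both groups in the series. ENU57022B6 was also the smaller of the 2 by the number of entries listed, with 6 against 12 for ENU57189B6.

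The sheet also listed groups outside the series in rows used by the series. Counting them, 5 of the 86 rows held 2 groups, against 2 within the series. The 3 added rows were row A of plate neuro2185, row A of plate neuro2194 and row D of plate neuro2204. Each held 6 entries of a group outside the series beside ENU57278B6, ENU57265B6 and ENU57022B6, respectively.

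Within 48 of the 87 groups with at least 2 libraries, the animal number, as read from the name, increased with the plate column.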
